A study of Mus musculus with 6 samples.

How the data were processed

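RNA-seq libraries were made from mouse CD4+ T cells of spleen and lymph nodes that had been sorted by flow cytometry into a CD11c+ and a CD11c- population, with 3 samples of each. Per the labels' protocols, RNA was extracted with a column kit for small samples (Qiagen RNeasy Micro) and converted to cDNA with a kit for very low RNA input (Clontech SMARTer Ultra Low), in which cDNA is amplified by PCR before sequencing. No molecular identifiers are named, so reads are not independent molecules, and read floors cover counting error only. The protocols do not name strand-specific counting, so reads of overlapping and antisense genes were not told apart.

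Per the submitters' processing notes, the authors' tools were Bowtie, SAMtools 1.2 and RSEM 1.1.13, and the genome build was mm9. The gene annotation and the scaling of the values are not given in the sources used here. Each of the 6 deposited files lists 21704 genes by symbol and Entrez identifier with a normalized signal per gene, a linear value with no fixed unit. The scale was worked out from the values. In each CD11c+ file a value of 1000 lay at the 75th percentile of the nonzero genes, and in the CD11c- files it lay at percentile 72.5 to 72.7, so that the upper quartile was 1139.5, 1121.3 and 1145.0 in CD11c- replicates 1 to 3. Nearly all values were whole multiples of a step that differed between libraries, which is the worth of 1 read. Between 94.9% and 95.7% of the nonzero values, and 97.8% to 97.9% of the low ones, lay within 0.05 reads of a whole number. The sums of these reads were 7077136, 2986735 and 3704728 in CD11c+ replicates 1 to 3 and 8884647, 10259479 and 11870864 in CD11c- replicates 1 to 3. A floor of 3 reads came to 7.56, 18.75 and 16.67 units in the CD11c+ libraries and 7.09, 5.87 and 5.11 units in the CD11c- libraries. Depth thus went with the group, and low genes were measured less precisely in CD11c+ cells.

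Samples were grouped by the sorted population in the labels, and the replicate number was taken from the sample title. Within the groups, no pair of libraries was the same library sequenced again: chi-square over degrees of freedom for recovered reads was 14.5 to 36.2, far above counting noise. Libraries made from 1 sample by separate amplification are not excluded by this.

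CD11c+ was compared with CD11c- by limma 3.58.1 in R 4.3.3. The deposited values were taken as log2(value + 1), and genes at 10 or more in at least 3 of the 6 libraries were tested. The fit had no covariates, and the variances were moderated by eBayes with a trend on mean level. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Where a group had no read, a lower bound of the fold was set against the mean floor of its libraries, 6.02 units in CD11c- and 14.3 in CD11c+. The exact permutation test of single genes cannot go below p = 0.1 with 3 samples against 3.

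The gene lists were fixed before the data were examined. They numbered 26 and held 385 distinct genes, of which 376 were found in the files. They covered T cell identity, naive and central memory, effector and memory activation, gut homing and chemokine receptors, integrins, innate and NK receptors of T cells, cytotoxic effectors, T cell cytokines and chemokines, cytokine receptors, the Th1, Th2, Th17, regulatory and follicular helper programs, innate-like T cells, inhibitory receptors, cell cycle, immediate early and stress genes, and interferon-stimulated genes. Lists for other cells that the sort could hold covered dendritic cells, B cells, monocytes and macrophages, NK cells, CD8 T cells, neutrophils, and erythroid cells with platelets. The 24 lists with at least 5 tested members were tested two-sided by camera with a preset inter-gene correlation of 0.01, which compares a list with the other genes, and adjusted over the lists. Calls were repeated with an estimated correlation and with fry, whose directional test asks whether a list moves on balance one way and whose mixed test asks whether members change in either direction. Current symbols were matched by Entrez identifier to a RefSeq gene table for 21561 genes. A GENCODE annotation, matched by symbol, gave transcript length and GC content for 92.3% of genes. That annotation is of another genome build than the files, so no coordinates are given.

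The genes named in the text follow a rule fixed before the data were examined. It takes Itgax and Cd4. It takes the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 100 in the higher group and no overlap between the groups. From each list it takes up to 3 called members with the largest change, or the most abundant member where none was called. It adds 21 genes of memory, gut homing and inflammation. Some genes that the rule takes are not reported here. Other genes that the text names were chosen after their values were seen, and are list members unless the text says otherwise.

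The limma and camera steps were tested on simulated libraries with the real genes, means and depths. Of the genes changed 2-fold, limma recovered 6.1%, and of those changed 4-fold it recovered 48%, with 2 unchanged genes called among 14706 tested. A list raised 2-fold was called, and 0 of 23 unchanged lists were. Genes were drawn independently and the lists were random, so this could not test whether the preset correlation is large enough for real lists. edgeR recovered 11% and 57.5% of the simulated 2-fold and 4-fold changes that passed its own filter, over 13001 genes. Its shares are of 91 and 87 changed genes and those of limma of 98 at each fold, so they are not directly comparable. In the simulation 2-fold changes were mostly missed. It changed far fewer genes than were called in the real data, so these shares do not carry over. The real lower calls had a median log2 fold change of −0.7.

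Alternatives set before the data were examined were other pseudocounts (10 and 0.1), no filter or a filter at 100, median-of-ratios, quantile and equal-sum scaling, other variance models, array weights, the replicate number as a block, leaving out each library, a fold minimum, and count models on the recovered reads (edgeR 4.0.16 and DESeq2 1.42.0). Alternatives added after seeing the data were scaling to the T cell identity list, leaving out chemosensory receptor genes, leaving out both libraries numbered 2, thinning all libraries to 2986735 reads, a correction for transcript length and GC content, and lists without genes shared with lists of other cells. Preparation and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.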

Results

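The transcriptomes of 2 sorted populations of mouse CD4+ T cells from spleen and lymph nodes were measured by RNA-seq. Both were taken from CD4+ cells, and they differed in surface CD11c, the integrin chain encoded by Itgax, which is best known from dendritic cells. Each population, CD11c+ and CD11c-, had 3 samples, called replicates 1 to 3. The labels do not say that these came from separate animals, so p-values measure the spread between these samples, which may be technical. The series concerns CD4+ memory T cells in intestinal graft-versus-host disease. It asks how CD4+ cells that carry CD11c, described there as central memory-like, differ in transcription from those that do not. The libraries held 2986735 to 7077136 reads in the CD11c+ group and 8884647 to 11870864 in the CD11c- group. Across genes, log2 values correlated at r = 0.867 to 0.894 among CD11c+ libraries, 0.962 to 0.978 among CD11c- libraries and 0.824 to 0.865 between the groups. Genes are not independent replicates, and these values describe spread only. The median SD of a gene's log2 value was 0.46 in CD11c+ and 0.26 in CD11c- libraries. Levels below are deposited normalized read counts, on a linear scale where 1000 lies at or near the upper quartile of detected genes.

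Itgax, the gene behind the sort, was 814.6 ± 112.6 in CD11c+ and 57.2 ± 31.3 in CD11c- cells (SD, n = 3 each), a log2 fold change of 3.95 ± 0.45 (SE; limma adjusted p = 0.00215). Cd4 was 9099 ± 2887 and 11830 ± 1177 and did not pass the test (limma adjusted p = 0.204). Genes typical of dendritic cells, macrophages and B cells were higher in the CD11c+ libraries, with list medians of 3.61, 5.67 and 2.19 on the log2 scale. Camera called these lists with its preset correlation but not with an estimated one (camera adjusted p = 0.64 for each). Cd3g and Cd3d, of the T cell receptor complex, were about 2-fold lower, and the T cell identity list had a median of −0.67. Among genes of T cell trafficking, Ccr9 was higher and Gpr15, Cxcr3 and Itgb1 were lower, while Ccr7, Itga4 and Itgb7 did not pass. The calls of Gpr15, Cxcr3 and Itgb1 ended after scaling to the T cell identity list. Of 14075 genes tested, limma called 2656, of which 1939 were higher and 717 lower in CD11c+ cells, while 5039 had an unadjusted p under 0.05. Increases were the larger: 1854 of the higher genes changed at least 2-fold and 732 at least 16-fold, against 87 and 5 of the lower genes. The groups did not overlap for 5715 genes, 40.6% of those tested, where chance gives 10%. The higher calls included 153 chemosensory receptor genes, of 273 tested and 1491 listed, a class singled out after the values were seen. Of all genes tested, 1939 of 14075 were higher. A single read was worth 6.25 and 5.5556 units in CD11c+ replicates 2 and 3 and 1.7039 to 2.3641 in CD11c- libraries. Low genes thus passed the filter at 10 units on fewer reads in those CD11c+ replicates, which can raise the share of 273.

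The count and its split depended on single libraries and on scaling. It was 419 (397 higher and 22 lower) without CD11c- replicate 3, 498 (454 and 44) without CD11c- replicate 2, and 1386 (1065 and 321) without CD11c+ replicate 2. The lower genes numbered 214 without CD11c- replicate 1. Quantile normalization gave 711 higher and 538 lower genes. Scaling to the T cell identity list gave 4340 higher and 18 lower, with the median of all genes at 0.62, against 0.04 as deposited.

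**Figure D1:**
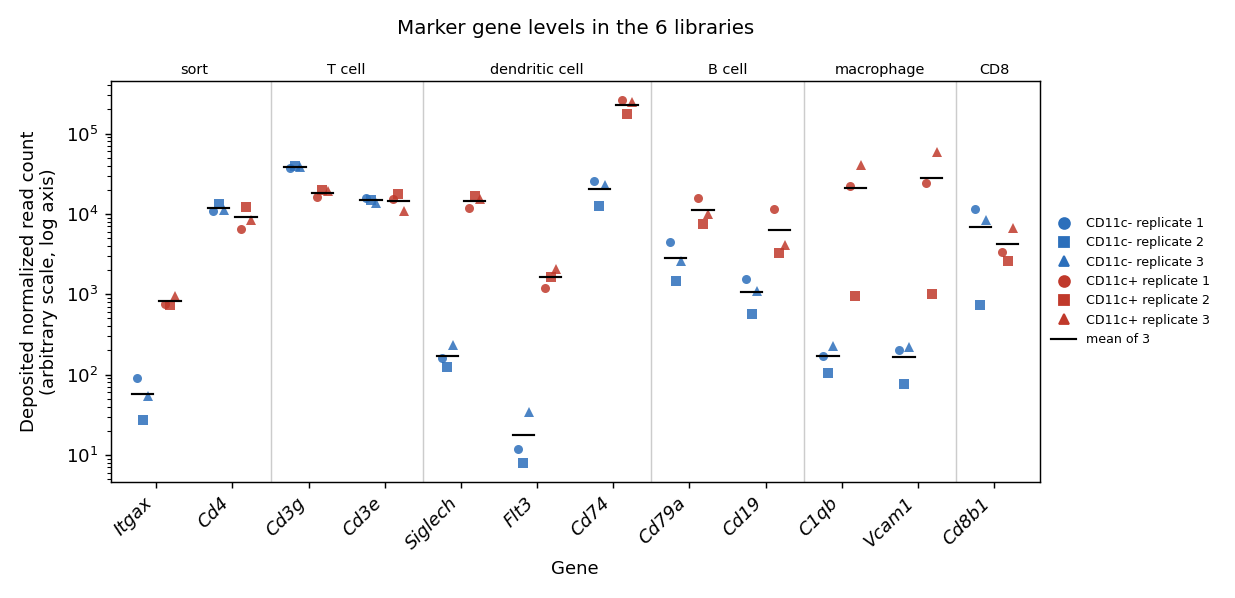
Levels of 12 marker genes in each library, as deposited normalized read counts on a log axis, with CD11c- libraries in blue, CD11c+ libraries in red, marker shape for the replicate number and a black line at the mean of 3. Siglech lay between 11947 and 16625 in CD11c+ libraries and between 125 and 232 in CD11c- libraries, while C1qb and Vcam1 were low in CD11c+ replicate 2 (950 and 1006) beside the other CD11c+ libraries.

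Of 22 tested dendritic cell genes, 19 were higher in CD11c+ cells and none was lower (21 higher when adjusted over the list alone; camera adjusted p = 6.7e-16, and adjusted p = 0.64 with an estimated correlation; fry adjusted p = 0.0023). Siglech, a lectin of plasmacytoid dendritic cells, was 14570 ± 2391 against 172.6 ± 54.2 (log2 fold change 6.42 ± 0.24, limma adjusted p = 1.75e-05). Flt3, the receptor that drives dendritic cell development, was 1625 ± 424 against 17.9 ± 14.1 (6.65 ± 0.55, limma adjusted p = 0.000519). Clec9a, a dead-cell receptor of cross-presenting dendritic cells, was 206.8 ± 40.9 and had no read in any CD11c- library, which makes it at least 34.3-fold higher. The invariant chain gene Cd74 was the most abundant member at 229100 ± 47580 against 20460 ± 6886. H2-Ab1, which encodes an MHC class II chain, was 100500 ± 36250 against 7285 ± 2596. Cd86, Cd83 and Ly75 did not pass the test, at 3096 against 1142, 6368 against 3869 and 229.3 against 299.0. Siglech, Flt3 and Clec9a were called with each library left out and under all 4 scalings.

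Of 18 tested monocyte and macrophage genes, 15 were higher and none was lower (17 higher when adjusted over the list alone; camera adjusted p = 3.1e-09, and adjusted p = 0.64 with an estimated correlation; fry adjusted p = 0.065). Vcam1, an adhesion molecule of splenic macrophages, was 24179, 1006 and 58889 in CD11c+ replicates 1 to 3 and 203.3, 76.3 and 218.1 in the CD11c- libraries. The complement gene C1qb was 22539, 950 and 40417 against 167.8, 105.7 and 230.0. The list lay 4.63 log2 units lower (median) in CD11c+ replicate 2 than in replicates 1 and 3. Mpeg1, a pore-forming protein of phagocytes, was more even at 2646 ± 827 against 35.4 ± 14.2 (6.23 ± 0.39, limma adjusted p = 0.00017), and its call held with each library left out. Cd14, the lipopolysaccharide co-receptor, was 1311 ± 1261 against 11.8 ± 10.2 (limma adjusted p = 0.0325). The calls ended without CD11c- replicate 2 or 3 for Vcam1 (limma adjusted p = 0.0683 and 0.0564) and without any library but CD11c+ replicate 2 for Cd14 (up to 0.108; 0.1 after quantile normalization).

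Of 15 tested B cell genes, 14 were higher and none was lower (14 when adjusted over the list alone; camera adjusted p = 2e-08, and adjusted p = 0.64 with an estimated correlation; fry adjusted p = 0.066). Spib, a transcription factor of B cells and plasmacytoid dendritic cells, was 1774 ± 124 against 280.0 ± 198.6 (2.89 ± 0.43, limma adjusted p = 0.00605). Blnk, an adaptor of the B cell receptor, was 2685 ± 385 against 447.0 ± 244.8 (2.73 ± 0.38, limma adjusted p = 0.0047). Ebf1, a transcription factor that specifies B cells, was 254.2 ± 171.1 against 36.2 ± 22.7 (limma adjusted p = 0.03), a call that ended without CD11c+ replicate 1 or 2 or CD11c- replicate 2 or 3 (up to 0.106) and after quantile normalization (1.40, 0.248). Cd79a, part of the B cell receptor, was 11130 ± 4193 against 2835 ± 1482. Among other cell types, 2 NK cell genes were higher and 1 lower of 13 (camera adjusted p = 0.48), and the higher ones, Tyrobp and Fcer1g, encode signalling adaptors that myeloid cells share. None of the 10 CD8 T cell genes was called by limma, with 0 when adjusted over the list alone (camera adjusted p = 0.63; lower without CD11c- replicate 2, 0.0186). Cd8b1, a chain of CD8, was 3390, 2600 and 6756 in CD11c+ replicates 1 to 3 and 11430, 735.8 and 8482 in CD11c- replicates 1 to 3, or 0.0559 to 1.04 times the level of Cd4. Of 4 tested neutrophil genes only Csf3r was higher, at 168.5 ± 166.9 against 5.07 ± 3.29 (limma adjusted p = 0.0497), a call that held without CD11c+ replicate 2 and ended without any other library (up to 0.158), after quantile normalization (0.3) and with either other pseudocount (0.0577 and 0.0623). None of 4 erythroid and platelet genes was called, and the alpha globin gene Hba-a2 was 4474, 281.2 and 15044 against 754.1, 260.3 and 315.2 (limma adjusted p = 0.139). Without CD11c+ replicate 2 the log2 fold change of Hba-a2 was 4.37 and past the threshold, against 2.75 with all libraries (limma adjusted p = 0.00652; edgeR adjusted p = 0.0363 and DESeq2 adjusted p = 0.0119 with all libraries).

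**Figure D2:**
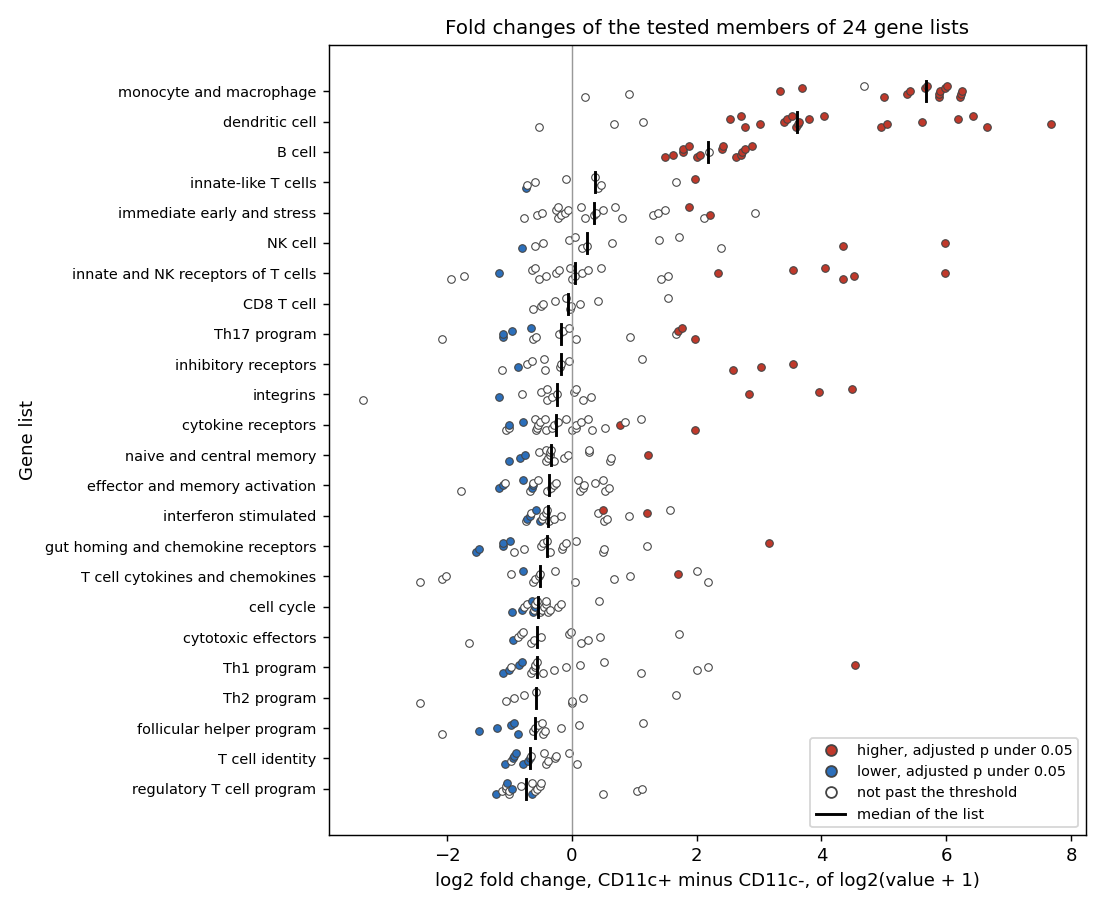
Log2 fold changes (CD11c+ minus CD11c-) of the tested members of 24 gene lists, each list on its own line, with filled points for genes past the limma threshold (red higher, blue lower), open points for the rest and a black bar at the list median. The monocyte and macrophage, dendritic cell and B cell lists have medians of 5.67, 3.61 and 2.19, and the medians of the other lists lie between −0.73 and 0.37; under scaling to the T cell identity list (not drawn) most of those medians are above 0.

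Of 16 T cell identity genes, 7 were lower in CD11c+ cells and none was higher (10 lower when adjusted over the list alone; camera adjusted p = 2.1e-06, and adjusted p = 0.64 with an estimated correlation; fry adjusted p = 0.065). The CD3 gamma gene Cd3g was 18460 ± 2056 against 38540 ± 1346, and it fell by 1.07 ± 0.15 on the log2 scale (limma adjusted p = 0.005). Cd3d, the CD3 delta gene, fell by 0.92 ± 0.14 (limma adjusted p = 0.00766), and Cd2, an adhesion receptor, fell by 0.93 ± 0.14 (limma adjusted p = 0.00597). Cd3e, the third CD3 chain, was 14670 and 14790 in the 2 groups (limma adjusted p = 0.904). The calls of Cd3g, Cd3d and Cd2 held with each library left out. They ended without both libraries numbered 2 (limma adjusted p = 0.0595, 0.0697 and 0.0628). They also ended after T cell identity scaling, which took the log2 fold changes to −0.48, −0.34 and −0.35 (limma adjusted p = 0.0963, 0.213 and 0.179). The list median stayed between −0.69 and −0.46 under the other scalings and was −0.08 under scaling to the list itself, which removes it by construction. Camera compares a list with the other genes, so under that scaling it still called 9 lists lower, most of them with medians near or above 0. In the same CD11c+ libraries the dendritic cell, macrophage and B cell genes made up 2.53%, 0.768% and 0.275% of reads, against 0.225%, 0.0613% and 0.0662% in CD11c- libraries, and the T cell identity genes 0.945% against 1.4%.

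The memory genes that the study's question concerns were mixed, in libraries where the T cell identity list had a median of −0.67 and the dendritic cell list 3.61. Of 18 naive and central memory genes, 1 was higher and 3 were lower, with the same counts when adjusted over the list alone (median −0.34, or 0.24 after T cell identity scaling; camera adjusted p = 0.092). That list was called lower with no filter on low values, with the length and GC correction, and without CD11c+ replicate 2 or CD11c- replicate 3 (camera adjusted p = 0.0178, 0.0338, 0.00834 and 0.044). With an estimated correlation it was not called (camera adjusted p = 0.78). Dapl1, a gene of resting T cells, fell by 1.01 ± 0.17 (limma adjusted p = 0.00884), and Id3, an inhibitor of E proteins, fell by 0.82 ± 0.20 (limma adjusted p = 0.0281). Igfbp4, an insulin-like growth factor binding protein, rose by 1.21 ± 0.21 (limma adjusted p = 0.0109) and was called with each library left out. Ccr7, the chemokine receptor of naive and central memory cells, was 17520 ± 8142 against 25430 ± 12220, and Il7r, the survival receptor of memory cells, was 2951 ± 963 against 3835 ± 760; neither passed (limma adjusted p = 0.341 and 0.292). Of 22 effector and memory activation genes, 5 were lower and none was higher (6 lower when adjusted over the list alone; median −0.37, or 0.21 after T cell identity scaling; camera adjusted p = 0.0064, or 0.0012 after that scaling, and adjusted p = 0.70 with an estimated correlation; fry adjusted p = 0.53). Itgb1 fell by 1.17 ± 0.18 (limma adjusted p = 0.00725), Cxcr3 by 1.11 ± 0.29 (limma adjusted p = 0.0315) and Il2rb, a receptor chain for IL-2 and IL-15, by 0.79 ± 0.16 (limma adjusted p = 0.017). Cd44, a marker of antigen-experienced cells, was 3472 ± 1313 against 2279 ± 231 (0.54 ± 0.26, limma adjusted p = 0.173; 1.12 and limma adjusted p = 0.0174 after T cell identity scaling; 0.0177 without CD11c+ replicate 1 and 0.0198 with array weights). Under that scaling none of the lower genes named here kept its call, and without CD11c- replicate 3 Dapl1, Id3, Cxcr3 and Il2rb lost theirs (limma adjusted p = 0.0578, 0.0942, 0.125 and 0.0845). Il2rb also lost its call without CD11c- replicate 2, Cxcr3 without CD11c- replicate 1 or CD11c+ replicate 2, Id3 without any library but CD11c+ replicate 1, and the effector list without CD11c+ replicate 1, after quantile normalization or with a filter at 100 (camera adjusted p = 0.054, 0.427 and 0.103). Id3, Cxcr3 and Il2rb were not called after quantile normalization either (limma adjusted p = 0.0762, 0.0669 and 0.073), nor Id3 after equal-sum scaling (0.0509).

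Beside the T cell identity median of −0.67, gut homing genes were mixed. Of 19 gut homing and chemokine receptor genes, 1 was higher and 5 were lower, with the same counts when adjusted over the list alone (median −0.40, or 0.19 after T cell identity scaling; camera adjusted p = 0.038, or 0.0037 after that scaling, and adjusted p = 0.70 with an estimated correlation; fry adjusted p = 0.55). Ccr9, the receptor for the small intestinal chemokine Ccl25 that gut-homing T cells and plasmacytoid dendritic cells carry, was 3301 ± 751 against 375.3 ± 127.1 (3.16 ± 0.29, limma adjusted p = 0.000701), and it was called with each library left out and under all 4 scalings. Siglech was 4.09 to 4.91 times the level of Ccr9 in the CD11c+ libraries and 0.321 to 0.938 times in the CD11c- libraries. Gpr15, a receptor for homing to the colon, was 143.1 ± 8.7 against 457.2 ± 239.3 (−1.53 ± 0.41, limma adjusted p = 0.0349), and Ccr10, a receptor of skin-homing cells, was 84.5 ± 18.2 against 252.1 ± 114.3 (−1.50 ± 0.44, limma adjusted p = 0.0473). The subunits of the gut-homing integrin did not pass the test: Itga4 was 1436 ± 482 against 1351 ± 424 (limma adjusted p = 0.892) and Itgb7 25120 ± 6411 against 32270 ± 403 (limma adjusted p = 0.205). Of 15 integrin genes, 3 were higher and 1 was lower, with the same counts when adjusted over the list alone (median −0.24, or 0.34 after T cell identity scaling, but mean 0.32; camera adjusted p = 0.45). The median of the integrin list ranged from −0.34 to 0.22 with 1 library left out. Beside Itgax, the higher genes were Itgad and Itga1. Itgad, the alpha D chain of macrophages, was 2902, 331.2 and 8322 against 85.1, 62.6 and 129.5, and Itga1, a collagen receptor chain, was 254.9 ± 98.7 against 39.2 ± 28.1 (limma adjusted p = 0.0189 and 0.0184). Ccr10 lost its limma call with each library left out in turn (adjusted p up to 0.148), Gpr15 without any but CD11c+ replicate 1 (up to 0.134), and Itgad and Itga1 without CD11c- replicate 2 (0.0761 and 0.072) or 3 (0.061 and 0.0802), Itga1 also without CD11c+ replicate 2 (0.0597). The gut homing list lost its call without CD11c+ replicate 1 or CD11c- replicate 3 (camera adjusted p = 0.16 and 0.05), after quantile normalization (0.332), with a filter at 100 (0.188), with array weights (0.0582) and with the length and GC correction (0.0723). Itgad and Itga1 lost their calls after quantile normalization (limma adjusted p = 0.0543 and 0.0744), and Gpr15 and Ccr10 after T cell identity scaling.

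**Figure D3:**
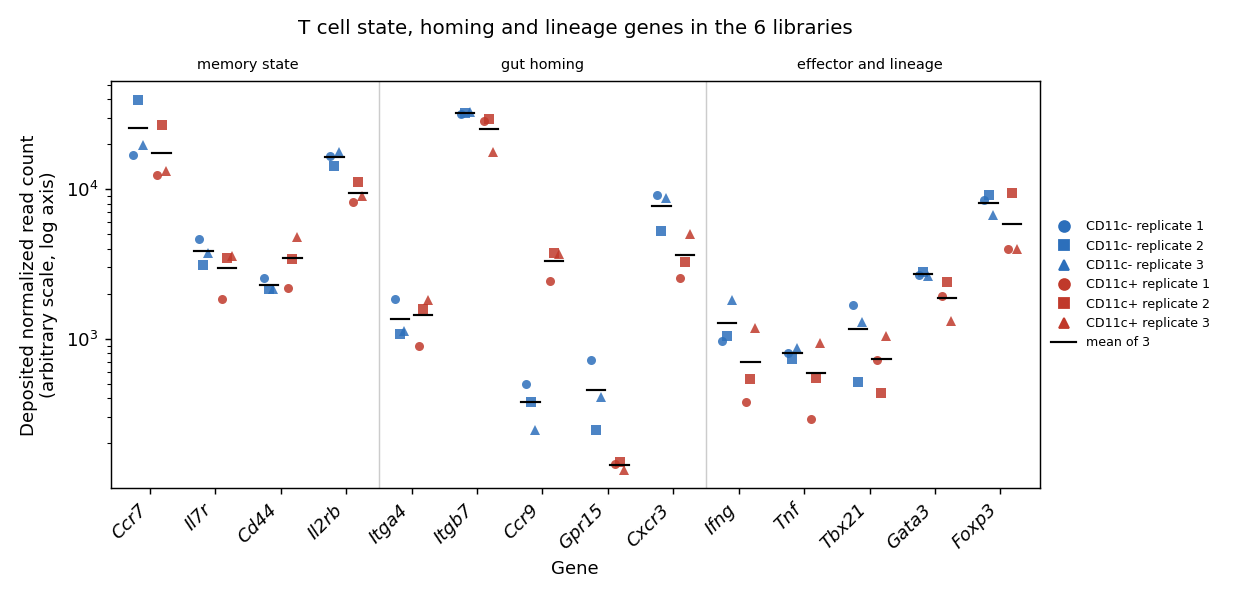
Levels of 14 genes of T cell state, homing and lineage in each library, as deposited normalized read counts on a log axis, with colours, shapes and mean lines as for the marker genes. Ccr9 (2435 to 3767 in CD11c+ and 247 to 501 in CD11c- libraries) and Gpr15 separate the groups without overlap, while Ccr7, Il7r and Itga4 overlap.

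The innate receptor genes that rose included several that myeloid cells share. Of 23 innate and NK receptor genes, 6 were higher and 1 was lower, with the same counts when adjusted over the list alone (median 0.05, or −0.25 after quantile normalization, and mean 0.92; camera adjusted p = 0.48). Of the 23, 7 are also in a list of another cell type, and the remaining 16 had a median of −0.10. In the same libraries the macrophage list had a median of 5.67 and the T cell identity list −0.67. Tyrobp, an adaptor of activating receptors in NK and myeloid cells, was 15300 ± 5046 against 269.2 ± 170.9 (5.98 ± 0.45, limma adjusted p = 0.000325). Fcer1g, an Fc receptor chain, was 8104 ± 6286 against 404.4 ± 262.3 (4.34 ± 0.74, limma adjusted p = 0.0102), and the Fc receptor gene Fcgr3 was 1930, 250.0 and 6317 against 96.9, 33.3 and 74.97 (limma adjusted p = 0.0201). Klrk1, which encodes the activating receptor NKG2D, was 576.8, 150.0 and 1389 against 799.0, 166.3 and 639.0 (limma adjusted p = 0.903). Of 13 inhibitory receptor genes, 3 were higher and 1 was lower, with the same counts when adjusted over the list alone (median −0.18, or 0.40 after T cell identity scaling, and mean 0.44; camera adjusted p = 0.50). Cd244, a SLAM family receptor, was 812.0 ± 275.1 against 70.7 ± 29.1 (3.54 ± 0.42, limma adjusted p = 0.00251). Lag3, a receptor that binds MHC class II, was 175.6 ± 135.9 against 18.4 ± 7.74, and Havcr2, the gene of TIM-3, was 452.6 ± 229.1 against 72.6 ± 26.6 (limma adjusted p = 0.0238 and 0.0127). Cst7, an inhibitor of granule proteases, was the 1 lower gene of 14 cytotoxic effectors, with none higher, also when adjusted over the list alone (2269 ± 607 against 4277 ± 790, limma adjusted p = 0.0289; list median −0.55, camera adjusted p = 0.14). The cytotoxic list was called lower after T cell identity scaling, with a median of 0.03 (camera adjusted p = 0.0012), with no filter (0.0318), and without CD11c+ replicate 3 or CD11c- replicate 2 (0.0253 and 0.0152). Its median was −0.07 without CD11c+ replicate 2 (camera adjusted p = 0.485). The CD8 T cell list stood at −1.38 in CD11c- replicate 2, relative to its mean over libraries, against 0.70 and 0.66 in CD11c- replicates 1 and 3. Of 9 innate-like T cell genes, Blk, a kinase of B cells and some gamma delta T cells, was higher (1023 ± 409 against 269.2 ± 132.8) and Slamf1 lower (1174 ± 200 against 1929 ± 113), with the same counts when adjusted over the list alone (limma adjusted p = 0.018 and 0.0242). That list had a median of 0.37, or −0.63 after quantile normalization, while camera ranked it lower (adjusted p = 0.84). Its median ranged from −1 to 0.64 with 1 library left out. Tyrobp, Fcer1g and Cd244 were called with each library left out. Fcgr3, Lag3, Havcr2, Cst7, Blk and Slamf1 lost the call without CD11c- replicate 2 (limma adjusted p = 0.0821, 0.0732, 0.0545, 0.0613, 0.0665 and 0.107) or 3 (0.0693, 0.0815, 0.0522, 0.117, 0.0702 and 0.0942), Lag3, Cst7 and Slamf1 also without CD11c- replicate 1 (0.0506, 0.0863 and 0.0567). Cst7 and Slamf1 lost it after T cell identity scaling. After quantile normalization Lag3 was at 1.58, against 3.03 as deposited (limma adjusted p = 0.31), and Fcgr3, Cst7 and Slamf1 also lost the call (0.0631, 0.0612 and 0.0529).

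Effector cytokine genes named in advance did not pass the test on the deposited values, beside a T cell identity median of −0.67. Ifng was 696.7 ± 419.3 against 1267 ± 467 and Tnf 593.7 ± 325.6 against 799.1 ± 64.2 (limma adjusted p = 0.129 and 0.301). Ifng was called lower without CD11c+ replicate 3 (−1.42, limma adjusted p = 0.0297) and with array weights (−1.14, 0.0496). Il10 was 308.2 ± 285.8 against 329.6 ± 221.2 (limma adjusted p = 0.725). Csf2 and Il17a were too low to test, with 0 reads in the CD11c+ libraries and 11 and 5 reads in the CD11c- libraries; differences were not detectable at this depth. Of 16 tested cytokine and chemokine genes, 1 was higher and 1 lower, or 1 and 0 when adjusted over the list alone (median −0.51, camera adjusted p = 0.45; after T cell identity scaling, median 0.07 and called lower, camera adjusted p = 0.0119). The median of that list ranged from −0.64 to −0.02 with 1 library left out. Tgfb1, which encodes a regulatory cytokine that many cell types make, was 1737 ± 309 against 537.9 ± 125.7 (1.70 ± 0.22, limma adjusted p = 0.00397), and Lta, the lymphotoxin alpha gene, was 888.0 ± 228.5 against 1497 ± 199 (limma adjusted p = 0.0465). Of 26 cytokine receptor genes, 2 were higher and 2 lower, or 1 and 2 when adjusted over the list alone (median −0.25, or 0.36 after T cell identity scaling; camera adjusted p = 0.14, or 0.0297 with no filter). Il1r1, the IL-1 receptor, was 118.6 ± 52.4 against 28.4 ± 7.6 and Il12rb1, an IL-12 receptor chain, 410.6 ± 77.4 against 822.7 ± 154.5 (limma adjusted p = 0.0466 and 0.024). Il23r, a receptor of Th17 cells, was 13.5 ± 13.9 against 9.91 ± 1.66 and Il18r1, the IL-18 receptor, 498.2 ± 238.5 against 518.5 ± 224.9 (limma adjusted p = 0.789 and 0.892). Tgfb1 was called with each library left out and under all 4 scalings, whereas Lta and Il1r1 lost the limma call without any library but CD11c+ replicate 1 (adjusted p up to 0.148 and 0.163) and Il12rb1 without CD11c- replicate 2 or 3 (0.0744 and 0.133). Lta and Il12rb1 also lost it after T cell identity scaling, and quantile normalization took Il1r1 from 1.98 to 0.50 (limma adjusted p = 0.558) and ended the call of Lta (0.0888). Lta was not called after equal-sum scaling (limma adjusted p = 0.0968) or by edgeR (adjusted p = 0.0546).

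The lineage regulators named here did not pass the test on the deposited values. Tbx21, of Th1 cells, was 731.2 ± 306.8 against 1162 ± 591 and Eomes, of cytotoxic cells, 496.9 ± 121.4 against 708.3 ± 253.9 (limma adjusted p = 0.388 and 0.334). Gata3, of Th2 cells, was 1882 ± 552 against 2704 ± 96.2 and Foxp3, of regulatory T cells, 5815 ± 3167 against 8101 ± 1254 (limma adjusted p = 0.0988 and 0.215). Gata3 was called lower with the length and GC correction and Foxp3 without CD11c+ replicate 2 (limma adjusted p = 0.0496 and 0.0156). Of 19 Th1 genes 1 was higher and 4 were lower (median −0.56 but mean 0.10, camera adjusted p = 0.13). The Th1 list was called lower after T cell identity scaling, with a median of 0.02 (camera adjusted p = 0.0061), with no filter (0.0244), and without CD11c+ replicate 3 or CD11c- replicate 2 (0.023 and 0.015). Its median was −0.21 without CD11c+ replicate 2 (camera adjusted p = 0.293). In CD11c- replicate 2 it stood at −0.42 relative to its mean over libraries, where the CD8 T cell list stood at −1.38. Of 16 Th17 genes 3 were higher and 4 lower (median −0.18, or 0.43 after T cell identity scaling, but mean 0.04; camera adjusted p = 0.45). Of 9 Th2 genes none was called (median −0.57, or 0.02 after that scaling; camera adjusted p = 0.21), and for these 3 lists the counts were the same when adjusted over the list alone. The Th2 median ranged from −0.77 to −0.16 with 1 library left out. The higher Th1 gene was Hlx, a homeobox factor, at 38.8 ± 24.6 and 1 read in the CD11c- libraries together (limma adjusted p = 0.0229). The higher Th17 genes included Tmem176a and Tmem176b, ion channel-like membrane proteins also found in dendritic cells, at 453.2 ± 113.3 against 140.2 ± 37.3 and 730.1 ± 209.0 against 207.9 ± 18.2 (limma adjusted p = 0.0163 and 0.0077). Of the Th2 list Stat6, the IL-4 signal transducer, was the most abundant at 6494 ± 1474 against 6413 ± 427 (limma adjusted p = 0.986).

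Most regulatory and follicular helper genes did not pass the test, beside a T cell identity median of −0.67. Of 18 regulatory T cell genes 4 were lower and none higher (8 lower and 1 higher when adjusted over the list alone; median −0.73, or −0.15 after T cell identity scaling; camera adjusted p = 0.00075, or 0.0561 after quantile normalization, and adjusted p = 0.70 with an estimated correlation; fry adjusted p = 0.29). That list stood at 0.27 in CD11c+ replicate 2, relative to its mean over libraries, against −0.77 and −0.64 in CD11c+ replicates 1 and 3. Without that library its median was −1.18. Nt5e, the ecto-enzyme CD73, fell by 1.21 ± 0.21, Folr4, a folate receptor family gene, by 1.04 ± 0.25 and Tnfrsf18, the GITR gene, by 0.96 ± 0.19 (limma adjusted p = 0.0107, 0.0268 and 0.0151). Of 15 follicular helper genes 5 were lower and none higher (6 lower when adjusted over the list alone; median −0.59, or −0.01 after T cell identity scaling; camera adjusted p = 0.00079, and adjusted p = 0.64 with an estimated correlation; fry adjusted p = 0.14). Sh2d1a, the SAP adaptor gene, fell by 1.49 ± 0.29, Slamf6, which signals through SAP, by 1.19 ± 0.23 and the co-stimulator gene Icos by 0.98 ± 0.26 (limma adjusted p = 0.0151, 0.0143 and 0.0355). Hlx, Tmem176a and the 6 genes named in this paragraph lost the limma call without CD11c- replicate 2 or 3 (adjusted p up to 0.107), Icos and Folr4 also without CD11c- replicate 1. Hlx and Folr4 lost it without CD11c+ replicate 3 too (limma adjusted p = 0.0655 and 0.0523), and Icos without CD11c+ replicate 2 (0.0503). After T cell identity scaling Nt5e and Sh2d1a alone of the 6 lower genes named kept it (limma adjusted p = 0.0348 and 0.0488). After quantile normalization Hlx was at 2.19, against 4.53 as deposited (limma adjusted p = 0.217), and Tmem176a, Folr4, Tnfrsf18 and Icos also lost the call (0.0625, 0.0739, 0.057 and 0.0813).

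Beside the T cell identity median of −0.67 and the dendritic cell median of 3.61, most cell cycle genes did not pass the test. Of 20 such genes, 5 were lower in CD11c+ cells and none was higher (9 lower when adjusted over the list alone; median −0.54, or 0.05 after T cell identity scaling; camera adjusted p = 5.6e-06, or 0.00025 after that scaling, and adjusted p = 0.64 with an estimated correlation; fry adjusted p = 0.13). Ccnb2, a mitotic cyclin, was 1849 ± 181 against 3606 ± 555 (limma adjusted p = 0.0101), the survivin gene Birc5 2284 ± 614 against 3881 ± 527 (limma adjusted p = 0.0368) and the mitotic kinase gene Plk1 1066 ± 104 against 1684 ± 356 (limma adjusted p = 0.0489). Of 23 immediate early and stress genes, 2 were higher and none lower, or 1 when adjusted over the list alone (median 0.35, camera adjusted p = 0.31, or 0.0186 after quantile normalization). They were Fosb, an AP-1 component, at 782.6 ± 236.0 against 215.6 ± 80.5 and the heat shock gene Hspa1a at 2187 ± 1186 against 530.2 ± 376.7 (limma adjusted p = 0.0151 and 0.0417). Of 20 interferon-stimulated genes, 2 were higher and 4 lower, or 3 and 5 when adjusted over the list alone (median −0.38, or 0.21 after T cell identity scaling; camera adjusted p = 0.18). Bst2, an antiviral membrane protein that plasmacytoid dendritic cells also carry, was 6713 ± 1042 against 2884 ± 224 (1.21 ± 0.16, limma adjusted p = 0.00365). Ifit1, an inhibitor of viral translation, was 894.1 ± 91.5 against 1472 ± 230 and Xaf1, a proapoptotic factor, 1426 ± 255 against 2237 ± 161 (limma adjusted p = 0.0305 and 0.0338). Bst2 was called with each library left out. Ccnb2, Birc5, Plk1, Fosb, Hspa1a, Ifit1 and Xaf1 lost the call without CD11c- replicate 3 (limma adjusted p = 0.0575, 0.148, 0.218, 0.0582, 0.0518, 0.131 and 0.141), all of these but Ccnb2 and Fosb also without CD11c- replicate 1 or 2. Birc5, Plk1, Ifit1 and Xaf1 lost it without CD11c+ replicate 2 too (limma adjusted p = 0.0801, 0.0952, 0.06 and 0.0783), Plk1 without CD11c+ replicate 3 (0.0973) and Hspa1a without CD11c+ replicate 1 or 3 (0.0581 and 0.102). The lower genes lost it after T cell identity scaling. Quantile normalization ended the calls of Birc5, Plk1, Hspa1a and Xaf1 (limma adjusted p = 0.0805, 0.091, 0.0671 and 0.0858), and equal-sum scaling those of Plk1 and Xaf1 (0.105 and 0.0545). Plk1 kept its call under none of the 4 scalings, with limma adjusted p = 0.0514 after median-of-ratios scaling, and lost it with a robust variance trend (0.051). Plk1 and Hspa1a were not called by edgeR either (adjusted p = 0.0597 and 0.0547), nor Hspa1a by DESeq2 (adjusted p = 0.0598).

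The 10 largest increases under the rule for named genes were Ptgis, Paqr9, Gfra2, Clec9a, Pir, Ltbr, Cd209d, Ttc39a, Slco2b1 and Epha2, ranked on the log2(value + 1) scale. Where CD11c- libraries had no read or 1 read, the rank rests partly on the added 1. Ptgis, which encodes prostacyclin synthase, was 484.5 ± 342.5, Gfra2, a receptor for neurturin, 619.1 ± 544.2 and Epha2, an ephrin receptor, 200.6 ± 86.3, each with 1 read in the CD11c- libraries together. Paqr9, Pir, Ltbr and Ttc39a had no read in any CD11c- library and were at least 83.9-, 35.1-, 35.8- and 29.9-fold higher on the CD11c+ mean. Single libraries differed widely: Paqr9 was 652.4, 31.25 and 833.3 in CD11c+ replicates 1 to 3, Ltbr 186.4, 87.5 and 372.2 and Ttc39a 312.3, 56.25 and 172.2. Gfra2 was 644.8, 62.5 and 1150 and Slco2b1 1166, 37.5 and 1683, whereas Pir, Cd209d and Epha2 were not lowest in replicate 2. Ltbr encodes the lymphotoxin beta receptor, which stromal and myeloid cells carry and lymphocytes lack. Cd209d, a C-type lectin, was 2005 ± 300 against 13.5 ± 9.7 (7.50 ± 0.68, limma adjusted p = 0.000712), and Slco2b1, an organic anion transporter, was 962.4 ± 841.6 against 3.01 ± 2.67 (limma adjusted p = 0.0158). The largest decrease was in the predicted gene Gm5409, at 27.9 ± 31.0 against 582.8 ± 193.7 (limma adjusted p = 0.0238), which is uncertain because predicted genes can share reads with near-identical copies. Of the other decreases, the entry listed as Kifc1, the name of a spindle kinesin, was 145.5 ± 32.9 against 478.4 ± 22.2 (limma adjusted p = 0.0101). Its Entrez identifier matched no current symbol, so which gene it measures is uncertain. Ms4a4b, a membrane protein of T cells, was 16840 ± 6572 against 47140 ± 13500 (limma adjusted p = 0.0148). U05342, Slc22a2, Atcay, Nhedc2, 4930486L24Rik and Gm4956 fell by 1.53 to 2.29 on the log2 scale, and Gpr15 was the remaining gene. The increases other than Slco2b1 were called with each library left out and under all 4 scalings. Slco2b1 lost its call without CD11c- replicate 2 or 3 and after quantile normalization (limma adjusted p = 0.0572, 0.0522 and 0.0785). Each decrease but Ms4a4b and Gm4956 lost its limma call both without CD11c- replicate 2 and without CD11c- replicate 3 (adjusted p up to 0.192). With single libraries left out, Ms4a4b lost the limma call only without CD11c- replicate 3 and Gm4956 only without CD11c- replicate 2 (adjusted p = 0.0528 and 0.0649). U05342, Slc22a2, 4930486L24Rik and Gpr15 lost it without CD11c+ replicate 2 too, Atcay and Gpr15 without CD11c+ replicate 3, and these 5 and Gm5409 without CD11c- replicate 1. After T cell identity scaling Gm5409, Kifc1, Nhedc2 and Gm4956 alone of the decreases kept it.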

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

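Scaling to the T cell identity list, leaving out receptor genes or both libraries numbered 2, thinning, the length and GC correction and lists without genes of other cells were chosen after the results were seen. Of 75 named genes called, 27 kept the call with each library left out, 33 under all 4 other scalings, and 23 under both. Of 9 lists called, 7 kept the call with each library left out and 6 under all 4 scalings. No called result reversed the direction of its test, although medians of the effector, gut homing and cell cycle lists were above 0 after T cell identity scaling (0.21, 0.19 and 0.05). Values of named genes, none of them called in either setting, changed sign 18 times with a library left out and 29 times in other settings, and list medians 11 and 26 times. The cause of the changes below was not tested, beyond the smaller number of samples or genes that some settings have by construction.

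Against 2656 genes called (1939 higher and 717 lower), leaving out 1 library gave 419 to 3592 genes (397 to 2713 higher, 22 to 908 lower). Counts (higher and lower) were 1647 (1000 and 647) with a filter at 100, 1249 (711 and 538) after quantile normalization, 2650 (2190 and 460) after equal-sum scaling, 1442 (1329 and 113) without a variance trend and 4476 (3226 and 1250) with array weights. They were 4358 (4340 and 18) after T cell identity scaling, 440 (415 and 25) without both libraries numbered 2, 1966 (1647 and 319) after thinning, 4173 (2982 and 1191) by DESeq2, where 3734 genes had no adjusted p, and 1941 (1854 and 87) with a log2 fold change of at least 1. edgeR called 2707, of which 2257 were shared with limma. With the replicate number as a block the counts were 1133 (928 and 205), with 11 lists (3 higher and 8 lower). Ifng (limma adjusted p = 0.0453) and the naive and Th1 lists (camera adjusted p = 0.044 for both) were called lower there. Deviations of same-numbered samples from their group means correlated at r = −0.42, −0.07 and −0.14, and no sample correlated best with its own number. With 3 samples per group this check cannot exclude that the numbers mark pairs, and the labels do not say what they mean.

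Against 9 lists called (3 higher and 6 lower), leaving out 1 library gave 7 to 12, with 3 higher throughout and 4 to 9 lower. There were 13 (3 and 10) without a filter, 7 (4 and 3) after quantile normalization, 12 (3 and 9) after T cell identity scaling, 0 (0 and 0) by camera with an estimated correlation and 1 (1 and 0) by fry. Effector and memory activation, gut homing and regulatory T cell lists were those that lost a call after quantile normalization (camera adjusted p = 0.427, 0.332 and 0.0561). A robust variance trend was not run for lists. Depth limits low genes most in CD11c+ replicates 2 and 3, where 1 read was worth 6.25 and 5.5556 units.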

Other observations

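The genes of the first 2 paragraphs and the test on displacement by 1 factor were chosen after the results were seen, as were the patterns weighed below and the share of receptor genes kept after thinning. The genes are single examples from outside the fixed lists and test no gene group. Klk1, a kallikrein, was 4413 ± 1566 against 45.2 ± 7.5 (6.52 ± 0.33 on the log2 scale, limma adjusted p = 5.3e-05), and Ly6d, a surface protein of lymphoid progenitors, B cells and plasmacytoid dendritic cells, was 14570 ± 2499 against 1648 ± 630 (limma adjusted p = 0.000712). Cox6a2, a cytochrome oxidase subunit, was 1710 ± 390 against 26.2 ± 24.7, and Runx2, a transcription factor, was 1093 ± 554 against 198.6 ± 63.1 (limma adjusted p = 0.00083 and 0.0151). Spic, a factor of red pulp macrophages, was 3471, 62.5 and 6567 in CD11c+ replicates 1 to 3, and Hmox1, which breaks down heme, was 21292, 1250 and 49361. Slc40a1, the iron exporter, was 31987, 593.8 and 30050, against means of 23.9, 278.8 and 117.7 for the 3 genes in CD11c- libraries.

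Igj, the antibody joining chain gene, was 19060 ± 1837 against 4855 ± 3260, and Sdc1, the plasma cell marker CD138, was 301.8 ± 130 against 72.4 ± 30.5 (limma adjusted p = 0.013 and 0.0292). Gimap7, a GTPase of lymphocyte survival, was 3555 ± 662 against 8494 ± 993, and Cd96, an adhesion receptor of T and NK cells, was 4347 ± 1010 against 9454 ± 981 (limma adjusted p = 0.0044 and 0.00862). Hopx, a homeodomain protein of effector and memory T cells, was 1405 ± 200 against 3426 ± 383, and Ms4a6b was 11110 ± 3126 against 29140 ± 1702 (limma adjusted p = 0.00358 and 0.00591). After T cell identity scaling these 4 lower genes were still called (limma adjusted p = 0.0447, 0.0435, 0.0261 and 0.0316), while Gimap4, Trat1 and Ms4a4b, lower as deposited, were not (0.123, 0.148 and 0.0613). Actb, the cytoplasmic actin gene, was 36491, 74794 and 174910 in CD11c+ replicates 1 to 3 and 164900 on average in CD11c- libraries.

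The 6 libraries can be divided into 3 and 3 in 10 ways, so no share of splits can fall below 0.05. The real split called 2656 genes and no other split called more than 0, so 1 of 10 splits called as many. Every other split mixes libraries of both sorts, so a difference between the sorts widens the spread within its groups. Few gene calls there were likely in any case, and this count does not decide about chance. For lists, 6 of 10 splits called at least as many as the real 9, and the highest other split called 16, so the number of list calls does not single out the sort. Whether structure among the samples or too small a preset correlation accounts for this was not tested. With an estimated correlation camera called 0 lists for the real split.

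For the first pattern, the higher dendritic cell, B cell and macrophage genes, a difference in depth or scaling was predicted to end most of the calls. Of the members called higher, 93.8% were still called after thinning and at least 81.2% under each of 4 scalings. These checks could hardly have ended the calls. The CD11c+ libraries were the shallower ones, and the scalings put the median of all genes at −0.16 to 0.62, against list medians of 2.19 to 5.67. A hypothesis is that the CD11c+ samples could hold plasmacytoid dendritic cells, and in replicates 1 and 3 macrophages. The dendritic cell list had camera adjusted p = 6.7e-16 (0.64 with an estimated correlation), and Siglech was at 14570. Cd74 at 229100 and H2-Ab1 at 100500 do not tell dendritic cells from B cells or macrophages. Of 15 B cell genes 14 were higher too, and whether B cells were present was not tested. That 0 of 23 listed dendritic cell genes are in another list reflects how the lists were drawn up. Activated T cells can carry some of these genes. A CD4+ CD3+ sort that excludes Siglec-H+ cells, F4/80+ cells, B cells and doublets would remove those cells. This was not tested, and transcription of these genes by CD11c+ T cells themselves, which would raise the same lists, stays open.

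The second pattern is the 153 chemosensory receptor genes that were higher. At equal depth, 25.7%, 56.9% and 59.2% of 1491 such genes had a read in CD11c+ replicates 1 to 3, and 23.7%, 8.7% and 8.4% in CD11c- replicates 1 to 3. Of all genes, 69%, 78.9% and 79% had a read in these CD11c+ libraries and 68.3%, 61.4% and 61.8% in these CD11c- libraries. Broader detection was thus not limited to receptor genes. Background reads, such as genomic DNA, predicted little overlap between replicates, and the odds ratio of detection in CD11c+ replicates 2 and 3 was 5.81 (4.61 to 7.34), between the limits set in advance for and against it, so this test cannot tell. The other CD11c+ pairs gave 8.8 and 6.26, and the CD11c- pairs 14.4, 9.86 and 15.7. CD11c+ replicate 2 with CD11c- replicate 1 gave 10, so such recurrence was not particular to CD11c+ libraries. Background could also recur in longer or more mappable genes, which was not tested, so it stays open. Over the 1491 genes, every CD11c+ library lay above every CD11c- library at equal depth, which met the bound set in advance. The smallest gap, between replicates 1, was 2 points with a counting error of 1.6 points. There, CD11c+ and CD11c- shares were 25% and 22.1% for olfactory genes and both 29.1% for vomeronasal genes. They were 20% and 26.7% for trace amine and 20% and 22.9% for bitter taste receptor genes. CD11c+ replicate 1 is thus not told apart from CD11c- replicate 1. Depth as the whole cause is argued against for CD11c+ replicates 2 and 3, which lay above every CD11c- library in each of these families. After thinning, 71.9% (110 of 153) of the receptor genes were still called, against 67.4% of all called genes and 76.1% of those called higher, and expression in CD11c+ cells was not tested.

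The third pattern is the lower level of T cell identity genes. If RNA of other cells displaced T cell RNA by 1 factor, the members would have moved alike, and their log2 fold changes had an SD 1.85 times their median standard error (0.35 against 0.19). The 95% interval of this ratio, 1.37 to 2.86 with members taken as independent, spans the bound of 1.5. After T cell identity scaling none of the 16 members was called by limma, also when adjusted over the list alone (3 with an unadjusted p under 0.05). That scaling uses these same genes and removes their shared change by construction, so few calls were likely with or without displacement. Displacement by 1 factor is therefore neither shown nor excluded as the cause. Transcript length and GC content did not account for it: the median was −0.66 after correction for both. Among the scalings that do not use the list, the median was −0.46 at its closest to 0. Those scalings put the median of all genes at −0.16 to 0.15, against 0.04 as deposited, so they could hardly have removed the pattern. Scaling to the list itself gave −0.08 by construction. Whether scaling accounts for the pattern is therefore not decided. A lower level in CD11c+ T cells themselves stays open.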
